A study of Mus musculus with 3 samples.

How the data were processed

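Chromatin of forebrain, midbrain and limb of CD-1 mouse embryos at embryonic day 11.5 was immunoprecipitated by the authors with an antibody against p300, from tissue pooled over about 150 embryos per library. Per the labels, fragments of 300 to 500 bp were selected on a gel and sequenced as 36 bp reads. The deposited reads of the first forebrain and midbrain runs held 38 bases, against that label. There was 1 library per tissue, from 2 sequencing runs in forebrain, 2 in midbrain and 3 in limb. Both forebrain and midbrain runs came from the same 2 flow cells or instrument runs, and the limb runs from 2 others. No input or control library was used here.

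The aligned reads, deposited as intervals on mm9 per the labels, give each read extended to 300 bp from the 5' end of its aligned bases or from the base before it, except for 45, 34 and 32 intervals of another length in forebrain, midbrain and limb. The aligner and the peak caller were not given in the sources used here. No extended interval occurred more than once on a strand. The coverage deposited by the authors is a signal, the number of extended reads over each step of 25 bp, without normalization. The peak lists deposited by the authors give a signal for each peak, its greatest height in extended reads, and counts, the number of extended reads that overlap it. Their false discovery rate per peak is of another unit, deposited without a statement of how it was estimated, and was not used as a measurement. Read sequences and quality characters, of another unit too, were deposited by the authors as they came from the sequencer. Per the file headers, the cutoff height at a false discovery rate of 0.01 was 7 in forebrain, 7 in midbrain and 6 in limb, which equalled the lowest peak height of each list.

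The files were checked against each other. Overlapping reads recounted from the aligned reads equalled the deposited counts for all 2453, 561 and 2105 peaks. On chromosome 19, recomputed coverage equalled the deposited value in 99.6% of 824233, 811902 and 607175 steps in forebrain, midbrain and limb. Heights recomputed at single-base resolution equalled the deposited height for 2096, 489 and 1878 peaks.

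Depth was 3629292 aligned reads in forebrain, 3530316 in midbrain and 2419480 in limb. By run it was 1634634 and 1994658 in forebrain, 1541202 and 1989114 in midbrain, and 1122050, 669606 and 627824 in limb. Reads whose aligned bases began at the same position and strand as those of an earlier read made up 0.0437%, 0.0402% and 0.0148%, although their extended intervals were not identical, and mitochondrial reads 0.0958%, 0.0681% and 0.156%, in the same order. The median peak held 13 reads in forebrain, 11 in midbrain and 9 in limb, which sets the precision of a ratio at a single peak. Intervals are exact conditional (Clopper-Pearson) intervals at 95% and cover counting error only. Reads carried no molecular identifiers and are not independent molecules.

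Overlap of lists meant at least 1 bp in common. Peaks of one list were placed 1000 times at randomly drawn aligned reads of their own library on the autosomes and chromosome X, keeping their width, and the p is the smaller tail doubled. Peaks per chromosome were compared with the share of the reads aligned to autosomes and chromosome X by two-sided exact binomial tests, adjusted by Benjamini-Hochberg over 60 tests. The plan had peaks per chromosome as values without a test, so those tests, the Fisher exact test of sharing with forebrain, and the comparison of first and later sequencing runs at the same peaks were chosen after the data were seen.

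Read density counted reads whose 5' end, shifted by 90, 93 and 79 bp in forebrain, midbrain and limb, lay in a peak, per 1000000 aligned reads (RPM). The shift came from fragment lengths of 180, 187 and 158 bp, estimated from the distance between strands. Flanks ran from 2000 to 10000 bp beyond each peak edge. A peak was called tissue-restricted when its own library had at least 3 times the RPM of the higher of the other libraries and the lower bound of the interval was above 1. There is no test between tissues. The rule for named regions took the 10 restricted peaks per tissue with the highest RPM in their own library, and the 5 regions in all 3 lists with the highest smallest RPM. The rule names no motifs, so every motif in the text was chosen after its values were seen.

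Sequence was taken from the reads themselves, since no mm9 genome was at hand. Reads of 36 bases that were aligned over nearly their whole length near any peak gave the majority base at each position, from 1 run in forebrain, 1 in midbrain and 2 in limb. Reads of the 3 libraries were pooled, so the bases of a window at a peak of any tissue can come from any library. Of 58989, 44518 and 41830 placed reads wanted in forebrain, midbrain and limb, 39859, 33569 and 38181 were found by name. Another set of limb reads, of 35 bases, was not used, since its names matched no aligned read. Overlapping neighbouring reads held the same base at 97.4% of positions on opposite strands and 97.6% on the same strand. In the windows of 400 bp at peak midpoints, 33.4% of bases were covered in forebrain, 40.4% in midbrain and 31.8% in limb, with GC contents of 46.8%, 48.6% and 49.7%. Flanking windows of 400 bp began 2000 bp from the peak edges.

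Consensus sites of 32 motifs, fixed before the data were examined, were counted on both strands. The test set in advance, a Fisher exact test on the share of windows holding a motif, follows coverage when sequence is partial. It was replaced after results had been seen. The statistic was then revised more than once, also after results were seen, because earlier forms gave small p-values for rare motifs or under unequal coverage. The final form sums, over the windows of one side, the occurrences less the covered places times the pooled rate. Window labels were permuted 100000 times, two-sided, for motifs with at least 10 occurrences over both sides. Labels were shuffled freely, without keeping flanks with their peak, and neighbouring windows are not independent, so these p-values may be too small. P-values were adjusted by Benjamini-Hochberg over 138 tests in 6 comparisons, and differences at an adjusted p under 0.05 are reported as such. Intervals of rate ratios came from 2000 bootstrap draws of windows. Peaks overlapping a peak of the other tissue were left out of each pair, so the rates of a tissue differ between comparisons.

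The steps were tested on simulated data. With 0, 20 and 100 planted overlaps, the placement test called 0, 20 and 20 of 20 simulated lists. The size rule called 0, 5.01, 21.7, 49.4 and 65.3% of forebrain peaks at true ratios of 1, 2, 3, 5 and 8. With 0, 50, 100 and 200 copies of TAATTA planted in forebrain windows, the motif test against limb windows called it in 0, 5, 10 and 10 of 10 simulations, and that against flanks in 0, 1, 8 and 10 of 10. The motif simulations filled windows with random bases, used fewer permutations and adjusted within a single comparison. Simulated peaks of the size rule were not chosen by peak calling. The rates for the size rule and the motif test are therefore not the power or error rates of the reported results.

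Alternatives set before the data were examined were the higher-ranked peaks of each list by height, thinning to the smallest library, other definitions of overlap, uniform random positions, each position and strand counted once, no shift, windows of 1 kb at peaks, reads outside all peaks as the scale, other folds for the size rule, and motif windows of 200 and 1000 bp. Alternatives chosen after seeing the data were thinning with the midbrain cutoff height required, thinning of autosomal reads to the density of chromosome X, leaving out the first sequencing run of each library, a motif rate less the rate from base composition, and peaks within 50 kb of each other counted once in the tests by chromosome or moved together in the test of peaks near a peak of another tissue. The Fisher exact test on windows had been set in advance as the main motif test, and became an alternative when it was replaced.

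Distances to transcription start sites, gene lists near peaks and gene lists between tissues were planned but not run, and the parts of the naming rule that rest on genes were not applied. The annotation at hand was for a later build than mm9, no coordinates were converted, and no genome was at hand in which to place the reads. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.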

Results

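Binding of p300, a histone acetyltransferase and coactivator found at active enhancers, was measured by ChIP-seq in 3 tissues of CD-1 mouse embryos at embryonic day 11.5. Forebrain, midbrain and limb gave 1 library each, from tissue pooled over about 150 embryos of both sexes. The libraries held 3629292 aligned reads in forebrain, 3530316 in midbrain and 2419480 in limb. Each tissue was a single pool, so no value below has a replicate error. Intervals are 95% and cover counting error only, and the tests describe these lists and libraries rather than the tissues in general. All coordinates are mm9. The annotation at hand was for another build, so no gene is named at any region. Forebrain and midbrain were sequenced on the same flow cells, and limb shared 0 flow cells with either, so limb and flow cell cannot be told apart in any comparison with limb.

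The number of p300 peaks in each tissue was compared first. Forebrain had 2453 peaks over 2001378 bp and limb had 2105 over 1436855 bp. Midbrain had 561 peaks over 402211 bp. Median peak width was 751 bp in forebrain, 676 bp in midbrain and 601 bp in limb. The highest forebrain peak reached 63 extended reads, against 25 in midbrain and 30 in limb, while median heights were 8, 8 and 7. Peak lists with different cutoffs and depths were put on the same scale by thinning every library to 2419480 reads. With at least 7 reads required, a mean of 1844.2 forebrain peaks and 379.1 midbrain peaks were left, against 1863 in limb. With a height of 7 required, the numbers were 1022.4, 187.0 and 1212. No test between tissues was possible with 1 library each.

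Peaks were unevenly spread over the chromosomes. Chromosome X held few peaks in all 3 tissues: 31 in forebrain, 4 in midbrain and 20 in limb. Its share of the reads aligned to autosomes and chromosome X would give 94.4, 21.9 and 67.9. The ratios to the expected number were 0.328 (0.224 to 0.465) in forebrain, 0.183 (0.050 to 0.466) in midbrain and 0.295 (0.180 to 0.454) in limb. Chromosome 13 was enriched in both brain tissues, with ratios of 1.44 (1.23 to 1.66) in forebrain and 1.94 (1.46 to 2.51) in midbrain. Its ratio in limb was 1.24 (1.03 to 1.47), which missed the threshold (exact binomial test, adjusted p = 0.117). The brain lists share peaks, with 275 of the 561 midbrain peaks overlapping a forebrain peak, so their results on chromosome 13 are not independent. Forebrain peaks were also more frequent on chromosome 18, at 1.40 times the expected number, and less frequent on chromosomes 15 and 17, at 0.551 and 0.698 times. The calls on chromosomes 18 and 17 ended in the higher-ranked part of the list (exact binomial test, adjusted p = 0.165 and 0.350) and with peaks within 50 kb of each other counted once (0.0636 and 0.465), and 21 of the 126 forebrain peaks on chromosome 18 lay in 1 Mb. Chromosome 12 passed only in the higher-ranked part of the forebrain list (1.43, exact binomial test, adjusted p = 0.0240), against 1.15 (0.323) over all peaks. Adjusted p-values on chromosome X, from two-sided exact binomial tests over 60 pairs of tissue and chromosome, were 1.39e-12 in forebrain, 6.44e-05 in midbrain and 3.03e-10 in limb. On chromosome 13 they were 6.44e-05 in forebrain and 8.85e-05 in midbrain. Neighbouring peaks are not independent, which makes these p-values too small; with peaks within 50 kb counted once, adjusted p from the exact test was 2.17e-08, 4.48e-04 and 3.56e-07 on chromosome X and 0.00412 and 0.00410 on chromosome 13. Reads were sparser on chromosome X than on autosomes, at 0.591, 0.598 and 0.492 times the autosomal density in forebrain, midbrain and limb. With autosomal reads thinned to that density, the ratio was 0.600 (0.405 to 0.860; exact binomial p = 0.00349) in forebrain, and the calls in midbrain (0.484, 0.130 to 1.27) and limb (0.866, 0.522 to 1.36) ended.

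**Figure D1:**
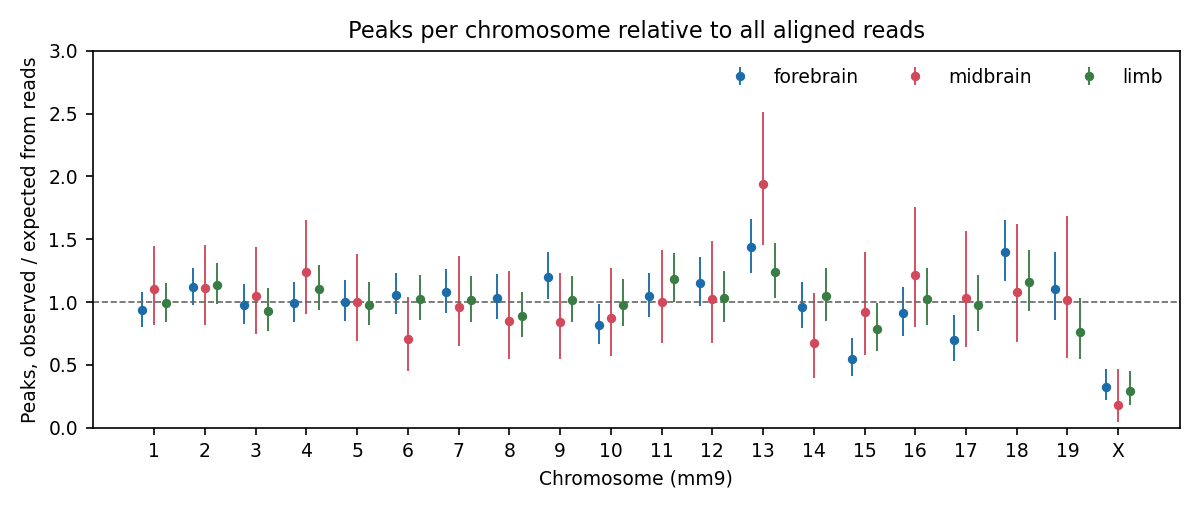
Peaks on each chromosome divided by the number expected from its share of the reads aligned to autosomes and chromosome X, for the 3 tissues. Points are ratios, bars 95% exact intervals, and the dashed line marks 1. Chromosome X lies at 0.328, 0.183 and 0.295 in forebrain, midbrain and limb, and chromosome 13 at 1.44 and 1.94 in forebrain and midbrain.

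Sharing of p300 sites between tissues was asked of the overlap of the lists. The brain tissues shared many peaks: 275 of the 561 midbrain peaks (49.0%) overlapped a forebrain peak, and 274 forebrain peaks (11.2%) overlapped a midbrain peak. Limb shared fewer, with 148 limb peaks (7.03%) overlapping a forebrain peak and 29 (1.38%) overlapping a midbrain peak. Most forebrain peaks (2052, 83.7%) and limb peaks (1949, 92.6%) were in no other list, as were 278 midbrain peaks (49.6%). All 3 lists held a peak at 21 regions. Random placement of the forebrain peaks at aligned reads gave a mean overlap with midbrain of 5.87, so that the observed number was 46.7-fold higher. The fold was 19.6 for forebrain and limb and 25.9 for midbrain and limb. Each pair had a two-sided p of 0.002, the smallest that 1000 placements can give. The placement shows that the lists coincide more than aligned reads placed at random. Without an input library it cannot tell shared p300 binding from other enrichment common to the libraries. Overlap with forebrain was more frequent among midbrain peaks than among limb peaks (odds ratio 12.7, two-sided Fisher exact p = 5.16e-107). Neighbouring peaks are not independent, which makes that p too small, and the difference was between a library that shares flow cells with forebrain and one that does not.

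Read density at the peaks of each tissue was compared between libraries. Forebrain peaks were 9.52-fold (9.41 to 9.64) above their flanks in the forebrain library, 3.52-fold (3.46 to 3.59) in midbrain and 2.60-fold (2.54 to 2.67) in limb. Limb peaks were 10.6-fold (10.4 to 10.7) above flanks in limb, 2.60-fold (2.54 to 2.67) in forebrain and 1.67-fold (1.62 to 1.73) in midbrain. Summed over the list, midbrain peaks were nearly as high in the forebrain library, at 8.18-fold (7.95 to 8.41), as in their own, at 9.24-fold (8.99 to 9.51). In limb they were 2.41-fold (2.27 to 2.55) above flanks. Reads in own peaks made up 1.02% of the forebrain library, 0.195% of midbrain and 0.951% of limb.

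**Figure D2:**
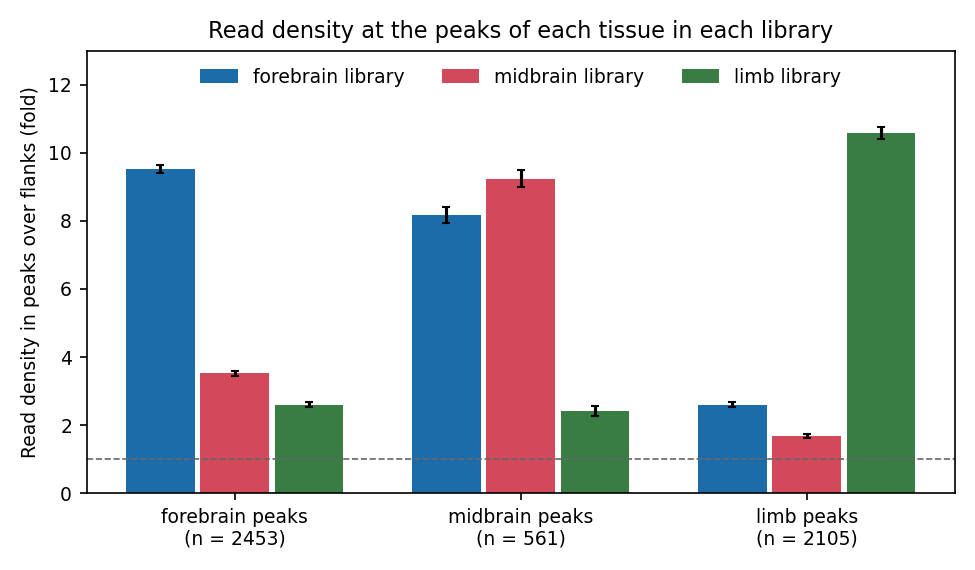
Read density in the peaks of each tissue divided by the density in their flanks, 2 to 10 kb away, in each of the 3 libraries; bars start at 0, error bars are 95% intervals of counting error, and the dashed line marks 1. Midbrain peaks reach 8.18-fold in the forebrain library and 9.24-fold in midbrain, while limb peaks reach 2.60-fold and 1.67-fold in the brain libraries and 10.6-fold in limb.

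Scaled to 1000000 aligned reads (RPM, reads per 1000000 aligned reads), forebrain peaks held 2.99 times (2.93 to 3.05) as many reads in forebrain as in midbrain and 3.81 times (3.71 to 3.92) as many as in limb. Limb peaks held 5.15 times (5.01 to 5.29) as many reads in limb as in forebrain and 8.32 times (8.05 to 8.61) as many as in midbrain. Midbrain peaks held 3.71 times (3.49 to 3.94) as many reads in midbrain as in limb, but 1.07 times (1.03 to 1.10) as many as in forebrain. These ratios are of sums over peaks. The median midbrain peak held 2.20 RPM in forebrain against 3.12 in midbrain, and 66.1% of midbrain peaks were higher in midbrain. Within the flow cells that the brain libraries share, midbrain peaks had mean densities of 3.39 and 3.53 RPM in the midbrain runs and 3.12 and 3.37 in the forebrain runs. Forebrain peaks had 4.14 and 4.21 in the forebrain runs and 1.35 and 1.43 in the midbrain runs. Across the 4686 merged peak regions, which are not independent replicates and were entered because at least 1 list held them, density in forebrain and midbrain correlated with r = 0.564 and rho = 0.521. The values were r = -0.256 and rho = -0.475 for forebrain and limb, and r = -0.146 and rho = -0.238 for midbrain and limb. A region entered through 1 list was chosen for high reads in that library, which by itself lowers these correlations. The negative values are therefore no evidence of opposed binding. Peaks were called on the same reads, which raises the density in their own library. In the 46 midbrain peaks whose first sequencing run alone reached the cutoff height, the ratio to forebrain was 1.06 from that run and 0.717 (0.641 to 0.800) from the later run. From all runs it was 0.866 (0.794 to 0.945), so these peaks are not typical of the list. Their ratio to limb went from 6.43 to 4.35. At 389 forebrain peaks chosen in the same way, the ratio went from 3.69 to 2.99 against midbrain and from 5.83 to 4.71 against limb. At 295 such limb peaks it went from 6.66 to 4.97 against forebrain and from 11.7 to 8.76 against midbrain. The ratio over all midbrain peaks had an interval that held 1 without a shift of the reads (0.970, 0.936 to 1.005) and in windows of 1 kb (0.975, 0.944 to 1.008), and was 1.048 (1.002 to 1.096) without the first sequencing run of each library.

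Peaks with p300 signal restricted to their own tissue were counted by a size rule: at least 3 times the density, in RPM, of the higher of the other libraries, with the lower interval bound above 1. Limb had 1339 such peaks (63.6% of its list, exact 61.5 to 65.7%), forebrain had 742 (30.2%, 28.4 to 32.1%) and midbrain had 32 (5.70%, 3.93 to 7.96%). At the depth of these libraries, the rule called 21.7% of simulated forebrain peaks with a true ratio of 3 and 65.3% at a ratio of 8. The counts are therefore of peaks with enough reads to pass. The simulated peaks were not chosen by peak calling. The real peaks were chosen for high reads in their own library, which can raise the counts, and the simulation does not measure by how much. With the libraries thinned to equal depth, the counts were 1059 in limb, 531 in forebrain and 13 in midbrain. Without the first sequencing run of each library, they were 692 in limb, 375 in forebrain and 10 in midbrain. Restriction of limb peaks cannot be separated from the flow cell.

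The strongest forebrain-restricted region was on chromosome 12 from 51221075 to 51222476. It held 83 reads in forebrain, 12 in midbrain and 3 in limb, and 22.9 RPM in its own library, 6.73 times (3.65 to 13.5) the midbrain level. On chromosome 14, the region from 13169875 to 13171401 held 76, 7 and 4 reads in forebrain, midbrain and limb. A region on chromosome 18 from 33712000 to 33713576 held 71 reads in forebrain against 3 in midbrain and 1 in limb, a ratio of 23.0 (7.56 to 114). Another lay on chromosome 4 from 5888950 to 5890926, with 18.7 RPM. The remaining 6 of the 10 named forebrain regions began at position 23182250 of chromosome 9, 22743950 of chromosome 6, 8043875 of chromosome 18, 78031375 of chromosome 13, 144199625 of chromosome 6 and 92018625 of chromosome 10. Own density ran from 14.9 to 22.9 RPM over the 10 regions, and the ratio to the higher other library from 3.09 to 23.0. The region on chromosome 10 overlapped a peak in all 3 lists, had the lowest ratio, and fell to 2.63 times without the first sequencing runs, which ended its call.

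Among the 10 named regions of each tissue, limb-restricted regions had the largest ratios. The largest rested on 2 reads in forebrain, with a wide interval that overlapped that of the largest forebrain ratio. The strongest limb region, on chromosome 18 from 78433825 to 78435726, held 67 reads in limb, 14 in forebrain and 7 in midbrain. It held 27.7 RPM in limb, 7.18 times (4.0 to 13.8) the forebrain level. A region on chromosome 6 from 84147175 to 84148501 held 47 reads in limb, 2 in forebrain and 1 in midbrain, a ratio of 35.3 (9.23 to 300). On chromosome 11, the region from 45363500 to 45364901 held 43, 2 and 1 reads in limb, forebrain and midbrain, a ratio of 32.3 (8.40 to 275). On chromosome 16 from 96069425 to 96070651, the limb library held 47 reads against 2 in forebrain and 3 in midbrain. The remaining 6 of the 10 limb regions began at position 171559800 of chromosome 2, 44859750 of chromosome 10, 88268200 of chromosome 11, 7943250 of chromosome 3, 25782850 of chromosome 12 and 69284525 of chromosome 18. Own density ran from 17.4 to 27.7 RPM over the 10 regions, and the ratio to the higher brain library from 3.71 to 35.3.

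Midbrain-restricted regions were weaker. The strongest, on chromosome 11 from 88087850 to 88089351, held 26 reads in midbrain, 7 in forebrain and 3 in limb, and 7.36 RPM in midbrain, 3.82 times (1.61 to 10.4) the forebrain level. On chromosome 2, the region from 116633550 to 116634476 held 24, 7 and 1 reads in midbrain, forebrain and limb. A region on chromosome 3 from 55769450 to 55770226 held 16 reads in midbrain, 3 in forebrain and 2 in limb, a ratio to limb of 5.48 (1.29 to 49.2). The remaining 7 of the 10 midbrain regions began at position 104402225 of chromosome 12, 49690475 of chromosome 3, 6907125 and 20187975 of chromosome 4, 68047450 of chromosome 5, 15479875 of chromosome 17 and 20753725 of chromosome 11. Own density ran from 4.25 to 7.36 RPM and the ratio from 3.08 to 5.48. Of the 10 regions, 4 still met the rule with the libraries thinned to equal depth, and 3 without the first sequencing runs.

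**Figure D3:**
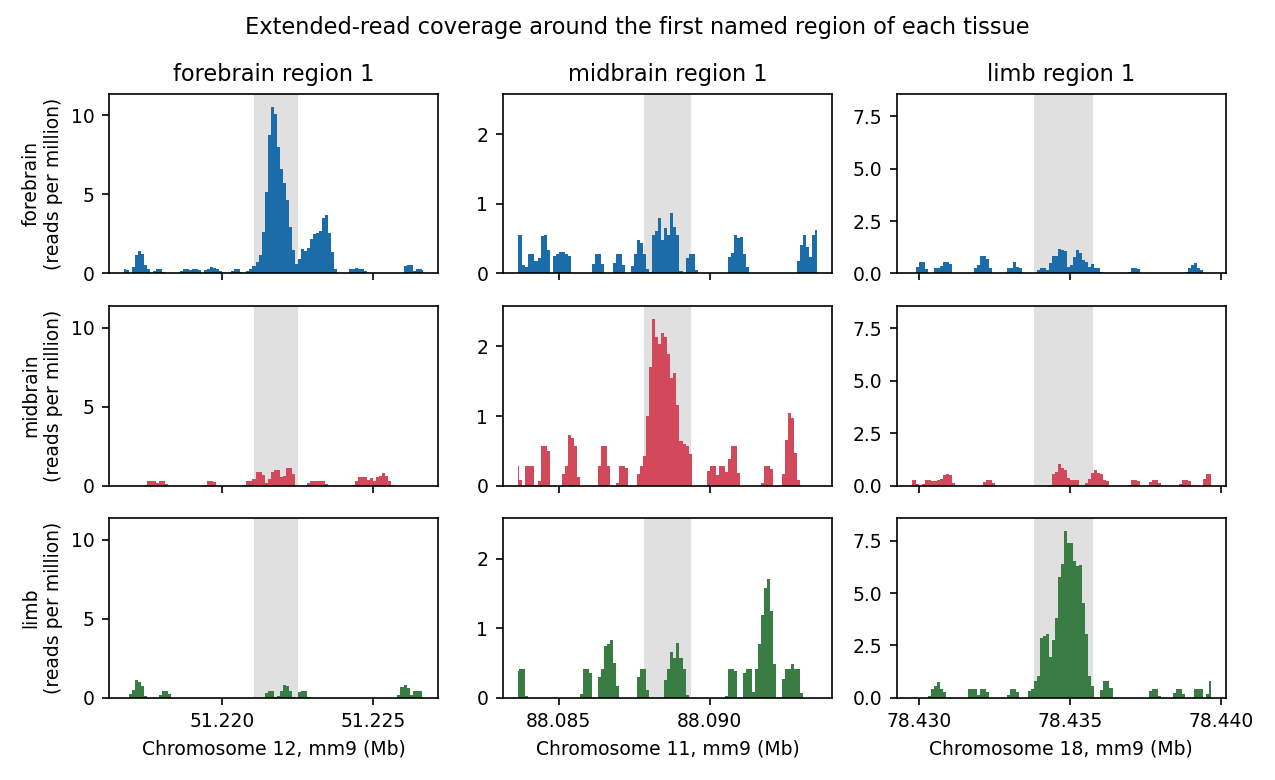
Coverage by extended reads, per 1000000 aligned reads, in steps of 100 bp over 10 kb around the strongest tissue-restricted region of each tissue (columns) in each library (rows); grey marks the deposited peak, and each column has its own vertical scale. The highest steps are 10.5 in forebrain, 2.39 in midbrain and 7.95 in limb, each in the region's own library.

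Of the 21 regions called in all 3 tissues, the 5 with the highest smallest density are named here. A region on chromosome 4 from 128392250 to 128394376 held 10.2 RPM in forebrain, 7.36 in midbrain and 8.27 in limb. On chromosome 13 from 52015675 to 52016726 the densities were 14.6, 6.23 and 5.79 in forebrain, midbrain and limb. On chromosome 18, the region from 55975225 to 55976701 held 7.16, 5.67 and 8.68 RPM in the same order. The other regions were on chromosome 4 from 97774675 to 97775901, with 12.1, 5.10 and 5.37, and on chromosome 11 from 113645725 to 113647701, with 11.0, 5.10 and 4.96. In windows of 1 kb the smallest density of the first of these regions was 4.53 and that of the last was 2.48 RPM.

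Sequencing runs of the same library, which are technical repeats, were compared over its own peaks. Forebrain peaks correlated between its 2 runs with r = 0.677 and rho = 0.413 over 2453 peaks, and midbrain peaks with r = 0.401 and rho = 0.208 over 561 peaks. Limb peaks gave r = 0.494, 0.479 and 0.408, with rho = 0.212, 0.219 and 0.174, for its 3 pairs of runs over 2105 peaks. Forebrain peaks were 9.56-fold and 9.50-fold above flanks in the separate runs, midbrain peaks 9.27-fold and 9.23-fold, and limb peaks 10.5-fold, 10.6-fold and 10.7-fold. Peaks above their flanks made up 99.7% and 99.9% in the forebrain runs, 99.1% and 99.5% in the midbrain runs, and 99.3%, 93.4% and 91.9% in the limb runs. Peaks are not independent replicates, and all were called on these same runs.

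Transcription factor motifs were compared at peaks of 2 tissues that overlap no peak of the other. The motifs named were chosen after their values were seen, from 32 fixed in advance. Forebrain windows held more copies than limb windows of the homeodomain core TAATTA, at 0.945 against 0.445 per covered kb (ratio 2.12, bootstrap interval 1.68 to 2.73). The same direction held for the SOX site ACAAWGG (2.05, 1.60 to 2.67), which SOX factors of neural progenitors recognise, and for the octamer ATGCWAAT of POU factors (5.98, 3.45 to 13.2). Limb windows held more copies of TTTATKG, the site of posterior HOX proteins that pattern the limb, at 0.922 against 0.290 per covered kb in forebrain (ratio of forebrain to limb 0.315, 0.240 to 0.414). The TEAD site GGAATGY was also more frequent in limb than in forebrain (0.537, 0.385 to 0.733). Of 24 motifs tested between forebrain and limb, 10 differed: 6 were higher in forebrain and 4 in limb. The others higher in forebrain were AACAAT (1.97), the MEIS site TGACAGS (1.61) and TAATCC, the site of bicoid-type homeodomain factors (1.68), and the others higher in limb were the FOX site TGTTTAC (0.560) and CCCNNGGG (0.539). Adjusted p was 9.86e-05 for TAATTA, ACAAWGG, AACAAT, ATGCWAAT and TTTATKG, from the smallest p that 100000 permutations can give (1e-05), and 0.000537 for TEAD. The call for CCCNNGGG ended when the rate from base composition was taken off (permutation test, adjusted p = 0.0519) and in windows of 200 bp (0.0646), and that for FOX in windows of 200 bp (0.113) and 1000 bp (0.0937). The call for TAATCC ended in the higher-ranked part of the lists (1.40, adjusted permutation p = 0.163).

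Midbrain windows were compared with the windows of limb in the same way. They held more of the SOX site ACAAWGG (2.33, 1.78 to 3.15), the POU octamer (3.97, 2.10 to 7.87), TAATCC (2.35, 1.67 to 3.22), MEIS (1.75, 1.21 to 2.44), AACAAT (1.72, 1.25 to 2.30) and the E-box CAGCTG of bHLH factors (1.38, 1.10 to 1.72). Limb windows held more of the posterior HOX site (ratio of midbrain to limb 0.351, 0.207 to 0.521), TEAD (0.256, 0.0991 to 0.449) and FOX (0.439, 0.186 to 0.803). In all, 9 of 24 tested motifs differed, 6 higher in midbrain and 3 in limb. The Fisher exact test on windows, set in advance, called 13, of which 11 were higher in midbrain and 2 in limb. That test follows coverage, which was higher in midbrain windows than in limb windows. Adjusted p was 9.86e-05 for ACAAWGG, the POU octamer, TAATCC, the posterior HOX site and TEAD, and 0.00717 for CAGCTG. TAATTA did not pass the test, with a ratio of midbrain to limb of 0.716 (0.438 to 1.07; permutation test, adjusted p = 0.258). FOX lost its call in windows of 1000 bp (adjusted p = 0.179), in the higher-ranked part of the lists (0.152) and under a Fisher exact test on windows (0.145), MEIS in windows of 200 bp (0.113), and CAGCTG in the higher-ranked part of the lists (0.159). In both comparisons with limb, the peak lists also came from libraries on different flow cells.

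Forebrain and midbrain windows, at peaks of libraries sequenced on the same flow cells, differed in 3 of 23 tested motifs. With 286 midbrain windows against 2179 of forebrain, large ratios could miss the threshold, as TEAD did (3.18, permutation test, adjusted p = 0.112). Forebrain windows held more TAATTA, at 1.02 against 0.328 per covered kb (ratio 3.13, 1.85 to 7.26; permutation test, adjusted p = 0.00325). Midbrain windows held more of the GATA site WGATAAG, at 0.405 against 0.122 (ratio of forebrain to midbrain 0.300, 0.157 to 0.655; permutation test, adjusted p = 0.00290) and more TAATCC (0.612, 0.426 to 0.95; adjusted p = 0.0439). The GATA call rested on 12 occurrences in midbrain windows and 28 in forebrain windows. Over all midbrain peaks the GATA rate was 0.169 per covered kb, against 0.185 in their flanks, so midbrain peaks were not enriched for it. The SOX site ACAAWGG was at 0.813 and 0.844 per covered kb in forebrain and midbrain (ratio 0.963, 0.675 to 1.52), and the POU octamer at 0.354 and 0.279 (1.27, 0.688 to 3.37). All 3 calls ended in the higher-ranked part of the lists, where TAATTA had a ratio of 2.0 (permutation, adjusted p = 0.228) and GATA 0.576 (0.501). TAATCC also lost its call in windows of 200 bp (0.867) and 1000 bp (0.229) and under the Fisher exact test (0.0820).

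**Figure D4:**
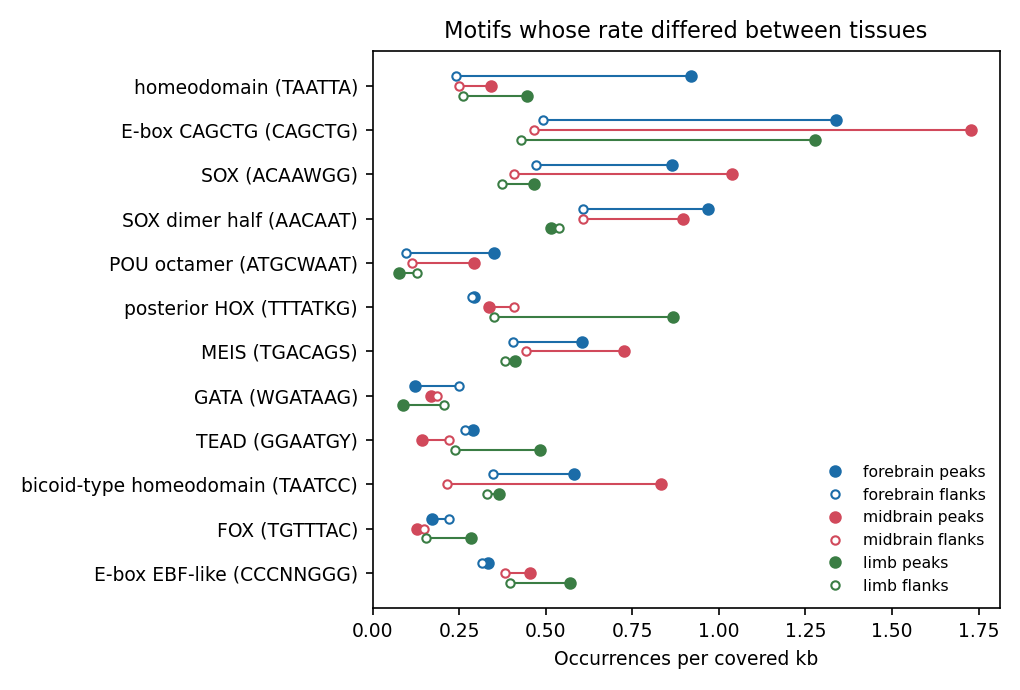
Occurrences per kb of covered sequence of the 12 motifs whose rate differed between the windows of any pair of tissues; filled points are 400 bp windows at all peaks of a tissue, open points their flanking windows, joined by a line. TAATTA lies at 0.919 in forebrain peaks and 0.241 in forebrain flanks, and the posterior HOX site at 0.868 in limb peaks and 0.352 in limb flanks.

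Against flanking sequence, 2 of the 3 E-boxes on the list, the sites of bHLH factors, were enriched at the peaks of all 3 tissues. CAGCTG was 2.73 times (2.09 to 3.75) as frequent as in flanks at forebrain peaks, 3.72 times (2.27 to 7.49) at midbrain peaks and 2.97 times (2.21 to 4.19) at limb peaks. CAGATG was 1.55, 2.84 and 1.70 times as frequent at forebrain, midbrain and limb peaks. The other E-box, CATATG, passed in no tissue, at 1.69, 0.979 and 0.929 times (permutation test, adjusted p = 0.140, 0.963 and 0.892). Forebrain peaks were enriched for TAATTA (3.81, 2.62 to 6.03), the POU octamer (3.67, 2.09 to 8.77), the RFX site GTTGCYAD (2.94, 1.90 to 5.33) and the ZIC site CAGCAGG (2.57, 1.74 to 4.35), and also for ACAAWGG (1.83), AACAAT (1.60), TAATCC (1.67) and the TCF-LEF site CTTTGAW (1.94). Limb peaks were enriched for the posterior HOX site (2.47, 1.74 to 3.65), RFX (3.30, 1.95 to 6.95), TEAD (2.03, 1.35 to 3.45), TAATTA (1.72, 1.17 to 2.82) and the NFI site TTGGCA (1.69). Midbrain peaks were enriched for ACAAWGG (2.55, 1.45 to 5.64) and TAATCC (3.88, 1.98 to 12.6). In forebrain 11 of 24 tested motifs differed from flanks, 10 of them higher at peaks; in midbrain 4 of 19, all higher; in limb 8 of 24, 7 of them higher. GATA was lower at peaks in forebrain (0.495, 0.300 to 0.844) and limb (0.428, 0.238 to 0.820), but these calls did not hold under most alternatives. They ended in windows of 200 bp (adjusted permutation p = 0.203 in forebrain and 0.0671 in limb), in the higher-ranked part of the lists (0.713 and 0.0510) and with the rate from base composition taken off (0.141 and 0.287), and in limb also in windows of 1000 bp (0.113). The Fisher exact test on windows turned GATA round, to 2.47 in forebrain (adjusted p = 9.72e-04) and 1.97 in limb (0.0622, which missed the threshold). That test counts windows whatever their coverage, which was 33.4%, 40.4% and 31.8% of bases at forebrain, midbrain and limb peaks and 6.82%, 7.45% and 7.09% in their flanks. In the higher-ranked part of the lists the calls for the POU octamer (2.72, adjusted permutation p = 0.0716), ACAAWGG (1.63, 0.0811), AACAAT (1.47, 0.158) and TCF-LEF (1.56, 0.227) in forebrain ended. So did those for TEAD (1.42, adjusted permutation p = 0.486), RFX (3.15, 0.0693), TAATTA (1.48, 0.449) and NFI (1.61, 0.144) in limb, and for ACAAWGG (2.93, 0.0664) and TAATCC (5.66, 0.0716) in midbrain. Windows of 200 bp ended those for TCF-LEF in forebrain (adjusted permutation p = 0.169), TAATTA (0.196) and NFI (0.157) in limb, and ACAAWGG (0.137) and TAATCC (0.0585) in midbrain. TAATCC in midbrain also ended in windows of 1000 bp (1.56, adjusted permutation p = 0.147), and NFI with the rate from base composition taken off (0.0529).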

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

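The tests of depth, cutoff height, library enrichment, base composition and limb sequencing batch, those of read density on chromosome X in each tissue by itself and with neighbouring peaks counted once, and that of sharing with forebrain, were chosen after the result was seen. So was the form of the motif test.

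Midbrain and limb differed in the share of peaks that overlapped a forebrain peak, 49.0% against 7.03% (odds ratio 12.7, Fisher exact p = 5.16e-107). The number of motifs that differed between windows was 3 for forebrain and midbrain, 10 for forebrain and limb, and 9 for midbrain and limb. The first pair had 2179 forebrain and 286 midbrain windows, and the second 2305 forebrain and 1957 limb windows. With such unequal numbers the counts do not rank how alike the tissues are.

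Midbrain had 561 peaks against 2453 in forebrain and 2105 in limb. Depth of the libraries was not the whole cause, since the smaller of the forebrain and limb numbers was still 1844.2 after thinning. Nor was the cutoff height, which was 7 in both brain libraries and so could set only limb apart from midbrain. At a height of 7 and the same depth there were 1212 peaks in limb and 187.0 in midbrain, with 1022.4 in forebrain. Weaker enrichment in the midbrain library stays open: at limb peaks, which neither brain library helped to choose, it lay 1.67-fold (1.62 to 1.73) above flanks against 2.60-fold in forebrain. A difference in p300 binding between the tissues may give the same values and was not tested apart from it.

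Chromosome X held fewer peaks than its reads would give in all 3 tissues. Peaks of 1 sequencing run stay open. The share of peak reads on X lay below the share of all reads on autosomes and X in 7 of 7 runs. But the list was called on all runs pooled, so a list with few X peaks gives a low share by itself. Lower read density on chromosome X, tested by thinning autosomal reads, was excluded as the whole cause in 1 of 3 tissues, forebrain, where the ratio stayed at 0.600 (0.405 to 0.860), and at 0.606 (0.403 to 0.879) with peaks within 50 kb counted once. In limb the ratio after thinning was 0.866 (0.522 to 1.36), an interval that holds both 1 and the forebrain ratio, so lower read density stays open there. In midbrain it was 0.484 (0.130 to 1.27), where 4 peaks are too few to decide. The pools held both sexes per the labels, and no biological explanation was tested.

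Motif rates differed between tissues in 22 calls over the 3 pairs. Base composition of the windows was not the whole cause: 21 of the 22 calls remained, in the same direction, once the rate it gives was taken off. The sequencing batch of the limb library cannot be told apart from the tissue in the comparisons with limb, since limb shared 0 flow cells with a brain library. The 3 calls between forebrain and midbrain were between peak lists of libraries that share flow cells. A difference between tissues in the factors that bind with p300 may underlie the rates and was not tested.

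Coverage also reached the cutoff height outside the peak lists. There were 624 such stretches in forebrain (15.7% of 3977), 556 in midbrain (44% of 1264) and 591 in limb (17.6% of 3357). The highest coverage outside the lists was 448 extended reads in forebrain, 452 in midbrain and 329 in limb. It lay at the same place on chromosome 2 in each library. The stretch ran from 98506113 to 98507763 in forebrain, 98506138 to 98507763 in midbrain and 98506138 to 98507713 in limb. A stretch from 35112538 on chromosome 9 also recurred, at 283, 283 and 225. The highest listed peaks reached 63, 25 and 30. Of all stretches outside the lists, 223, 212 and 449 in forebrain, midbrain and limb were at the cutoff in both other libraries, and 188, 182 and 251 were on contigs without a place.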

How the results depend on the processing

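Alternatives chosen only after the data were seen were thinning with the same height required, thinning of autosomal reads to the density of chromosome X, leaving out first sequencing runs, taking off the rate from base composition, and counting peaks within 50 kb once or moving them together. The Fisher exact test on windows was the motif test set in advance, and became an alternative after it had been replaced. Overlap and nearness of lists kept direction and call in 15 of 15 alternatives, with folds of 42.9 to 329 for forebrain and midbrain, 16.4 to 47.3 for forebrain and limb, and 19.99 to 44.5 for midbrain and limb. Correlations between runs stayed the same in 5 of 5, where the only alternative counted each position and strand once. Repeated positions made up at most 0.0437% of reads, so that alternative could change little, also for the density ratios and restricted counts. Of the density ratios, 16 of 30 stayed in the main interval. Within a fixed factor of the main count were 12 of 21 restricted counts and 22 of 30 motif counts. Of 30 peak numbers and chromosome ratios, 18 kept that factor or, for the ratios, their call. Of the ratios of named regions, 103 of 120 still met the size rule. Of the motif values, 183 of 225 kept direction and call, and 23 of 25 shared densities stayed in the main interval. For all values below, the cause was not tested unless given.

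Among the higher-ranked peaks of each list there were, by construction, 1226, 280 and 1052 in forebrain, midbrain and limb. Thinned with the same height required, there were 1022.4, 187.0 and 1212, in forebrain and midbrain from fewer reads and in limb, which was not thinned, from the height of 7. With autosomal reads thinned, the X ratios of midbrain and limb were 0.484 and 0.866, no longer past the threshold. Forebrain calls on chromosomes 17 and 18 ended among higher-ranked peaks (0.733 and 1.33) and with peaks within 50 kb counted once (0.785 and 1.32), while those on 13, 15 and X were kept and chromosome 12 passed only among higher-ranked peaks (1.43).

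Without a shift of reads, density ratios were 2.82 for forebrain to midbrain and 3.56 for forebrain to limb at forebrain peaks, 3.27 for midbrain to limb at midbrain peaks, and 4.72 and 7.57 for limb to forebrain and midbrain at limb peaks. In windows of 1 kb they were 2.71, 3.34, 3.08, 4.22 and 6.36 in the same order. Midbrain to forebrain at midbrain peaks fell to 0.970 (0.936 to 1.005) without a shift and 0.975 (0.944 to 1.008) in windows of 1 kb, intervals that hold 1, so the difference was lost rather than turned round. Without first sequencing runs, limb to forebrain and to midbrain were 4.91 and 7.91.

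Restricted peaks numbered 411 in forebrain and 19 in midbrain at 5 times, 13 in midbrain after thinning and 21 in windows of 1 kb. Among the higher-ranked peaks, which are fewer, they numbered 14 in midbrain (5.0% of the list) and 829 in limb (78.8%, a higher share). Without first sequencing runs, which leaves fewer reads, there were 375 in forebrain, 10 in midbrain and 692 in limb.

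Motif counts among higher-ranked peaks, which are fewer, were 0 for forebrain against midbrain and 6, 2 and 3 for forebrain, midbrain and limb against flanks. Midbrain against flanks had 2 in windows of 200 bp. The Fisher exact test on windows, which follows the unequal coverage, gave 24, 19 and 23 against flanks and reversed GATA, to 2.47 in forebrain and 1.97 in limb, where it missed the threshold. Of the 22 calls between tissues, 19 were kept in windows of 1000 bp, 18 in windows of 200 bp, 20 under the Fisher exact test, 21 with base composition taken off and 16 among higher-ranked peaks.

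Distances to start sites and gene lists were not run under any setting, for want of an annotation on mm9. No paired analysis was possible because each tissue had 1 library and the labels pair none. Single peaks held medians of 13, 11 and 9 reads. Of the 10 named midbrain regions 4 met the rule after thinning, 3 without first sequencing runs and 7 in windows of 1 kb.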

Other observations

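The test on locally moved peaks was set out before its result was seen, but after the same neighbours had been compared with random placement. Moving neighbours together was chosen after that result was seen, and the stretches of 1 Mb were chosen after their values were seen.

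Peaks of all 3 tissues gathered on chromosome 18 from 55000001 to 56000000, with 21 forebrain, 6 midbrain and 15 limb peaks. Limb peaks gathered on chromosome 6 from 52000001 to 53000000, with 18 peaks against 4 in forebrain and 0 in midbrain, and on chromosome 18 from 69000001 to 70000000, with 12 against 6 and 0. Forebrain peaks gathered on chromosome 9 from 61000001 to 62000000, with 14 peaks against 1 in midbrain and 6 in limb, and on chromosome 3 from 34000001 to 35000000, with 13 against 2 and 1. Midbrain peaks gathered on chromosome 2 from 77000001 to 78000000, with 6 peaks and 0 in either other tissue. Within each list, 31.3% of forebrain, 14.6% of midbrain and 33.0% of limb peaks lay within 50 kb of another peak of the same tissue. Random placement gave 10.2%, 2.40% and 9.20% (3.07-fold, 6.08-fold and 3.59-fold; permutation p = 0.00995 in each tissue, the smallest that 200 placements can give).

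Peaks of different tissues may share loci beyond the regional density of peaks, as a hypothesis. With overlapping peaks left out, 288 forebrain peaks lay within 50 kb of a limb peak, against a mean of 204.3 after moving each peak by 0.2 to 1 Mb, a fold of 1.41. The fold was 3.04 for forebrain peaks near midbrain peaks (92 against 30.3) and 1.61 for midbrain peaks near limb peaks (76 against 47.2). Each pair had a two-sided p of 0.002, the smallest that 1000 moves can give. Neighbouring peaks of a list are not independent; with peaks within 50 kb moved together the folds were 1.41, 3.05 and 1.60 in the same order, and each p was again 0.002. Which genes lie at these loci was not analysed here.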
